A study of Oryzias latipes with 31 samples.

How the data were processed

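Gene expression was measured in whole newly hatched Japanese medaka on 31 single-colour (Cy3) Agilent arrays of a custom design, 1 pool of 3 fish per array. Embryos had been kept from their first day in water, in dispersant, or in dilutions of diluted bitumen, with the solutions renewed daily for up to 16 days, and fish were taken within 24 h of hatching. The oils were Access Western Blend (AWB) and Cold Lake Blend (CLB). Each was prepared as a water accommodated fraction (WAF) or, with dispersant, as a chemically enhanced one (CEWAF), and each preparation was given at a low (Lo) and a high (Hi) level.

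Per the file headers, each scanner file held an intensity for every spot, background subtracted and detrended within the array by the Feature Extraction software and not normalised between arrays. Per the file headers, the same files also held the raw intensity of the spot and of its local background as pixel medians, and other columns of 0 or 1 that marked spots well above background, saturated spots and outlier spots. The deposited table of the series held log2 values. Per the submitters' processing notes, limma had been used, and the table's columns shared the same quantiles, so that the authors' values were treated as quantile normalised. The authors' background step was not given in the sources used here.

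Each array carried 43803 probe spots besides 1417 control spots, for 22773 distinct probes, of which 3948 were printed once, 16620 were printed 2 times and 2205 were printed 3 times. Control spots and spots marked as outliers were left out, and no spot was saturated. The background-subtracted intensity was taken to log2, the array's 75th percentile was subtracted, and the spots of a probe were averaged. Levels in the text are therefore log2 signals relative to the 75th percentile of the array. A probe was kept when it was well above background on at least 3 of the 31 arrays, which left 22577 probes. The signal at the 75th percentile ranged from 628 to 2687 (median 1497), and 80.5% to 98.5% of the spots of an array (median 95.2%) were well above background. The arrays' number limits the precision, and all p-values measure the spread between pools, not between single fish. The sample descriptions give at least 15 eggs per jar and 30 eggs per treatment, so pools of a treatment may have shared a jar. The jar of each pool was not given. The tests treat pools as independent, so an effect of the jar cannot be told from that of the treatment.

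The files carry no gene symbols. Probes were named through their RefSeq accessions, without version, from the gene table of the medaka assembly ASM223467v1, used for names alone. Of 22673 accessions, 9772 matched 1 gene and 5244 of those carried a symbol. The remaining probes were tested and counted, but are not named in the text. Of the probes, 3948 were marked as cross-hybridising in their names, 648 of them with a symbol, and genes read through such a probe are pointed out. The symbol gb belongs to several genes of the table. It is used here for the single gene that the naming rule picked.

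All comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test), with Benjamini-Hochberg adjustment over the 22577 probes and a threshold of 0.05 on the adjusted p. Files were read and written with the package data.table in version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The 5 comparisons of phenotype used the 4 phenotype groups of the labels and all 31 arrays. The comparisons of exposure used the 10 treatment groups and all 31 arrays. The comparison inside WAF Hi used treatment groups divided by phenotype. Values after ± are standard errors of the difference unless marked SD, and intervals cover 95%. Counts of pools that were higher, lower or shifted refer to the mean of the other group, unless all its pools are named.

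30 gene lists were fixed for the tissue and the exposure. They were tested for 7 comparisons with camera (preset correlation 0.01, 168 tests adjusted together) over 9472 genes, each read through its brightest probe. 24 lists had at least 5 measured members. The other 6 (aryl hydrocarbon receptor battery, other phase I and II metabolism, exocrine pancreas and digestion, intestine, hatching enzyme, epidermis and keratin) had fewer and are given as single genes. List entries given by description instead of by symbol matched nothing, and rhob and anxa10 were kept out of the lists. A member's result is also given adjusted over the list alone. Each list was tested again with a correlation estimated per list and with fry. The estimated correlation left none of the 21 calls of camera, and neither did fry.

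Genes were named by a fixed rule. For malformed against normal oil pools, and for malformed oil, normal oil and dispersant pools against water, these were the 8 largest rises and the 8 largest falls among genes with a symbol that passed the threshold and lay well above background on at least 3 arrays of the higher group. To these was added, from each list with a passing member, the member with the smallest p. For the other comparisons the rule took the 5 largest rises and the 5 largest falls. Where fewer than 3 genes passed, the 3 with the smallest p were named as not passing. The gene cyp1a was always named, and cyp1b1, cyp1c1 and ahrr were not found by symbol. Other list members are cited as examples of their list. No named gene had another probe to compare, so agreement between probes of a gene could not be checked. The groups, comparisons, lists, tests, naming rule and first set of alternatives were chosen before the data were examined. The values of called lists within each preparation were added afterwards.

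Those alternatives were quantile normalisation, normexp background correction (offset 50) followed by quantile normalisation, the authors' values, no filter on dim probes, and a stricter filter (22084 probes). They also covered slide as a fixed or a random block, the replicate number as a block, a fit to the compared arrays alone, a change of at least 2-fold, and each of the 31 arrays left out in turn. Normexp was run on the pixel medians, since the files held no mean signal. Added after seeing the data were scan day as a block, each scan day alone, a fit without the 2 arrays least correlated with the others, a fit without the 2 WAF Hi pools labelled normal, and the level of the hatching enzyme gene hce as a covariate. Per the file headers, the arrays lay on 8 slides scanned on 2 days. No slide and no scan day held both water and dispersant arrays, so these controls could not be compared within a batch.

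The fits were tested on simulated data, in which 200 probes were shifted by 1.5-, 2- or 4-fold. Noise was drawn for each probe on its own, with the probe's spread within treatment groups. Slide differences shared by many probes and differences between treatment groups of the same phenotype were left out. The recoveries may therefore overstate those on the real arrays. At 2-fold, 82.1% of the shifted probes were recovered for malformed against normal oil pools and 77.6% for normal oil pools against water. The recovery was 65.7% for WAF Lo against water, 62.7% for CEWAF Lo against water, 92.5% for AWB against CLB, 50.7% for dispersant against water, 56.7% for the interaction with the oil and 35.8% inside WAF Hi.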

Results

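The 31 arrays comprised 4 pools of fish kept in water, 3 pools kept in dispersant, and 3 pools in each of the 8 combinations of oil (AWB or CLB), preparation (WAF or CEWAF) and level (Lo or Hi). The series description mentions more water pools than the 4 that have an array here. By the labels, all 4 water pools were normal and all 3 dispersant pools malformed. Among the 24 oil pools, 14 were labelled normal and 10 malformed, where malformed fish showed signs of blue sac disease (oedema of the yolk sac and heart region). All 12 Lo pools were normal. All 6 CEWAF Hi pools and 4 of the 6 WAF Hi pools were malformed, whereas AWB_WAF_Hi 1 and CLB_WAF_Hi 3 were labelled normal, although the design text describes the fish at the high level as malformed. Arrays of the same treatment group correlated at 0.968 to 0.992 over the probes. The largest component of variation between arrays (21.5% of the variance) followed the slide, which explained 80.2% of it, against 0.386% for the phenotype. With treatment group in the model, 5353 probes differed among slides.

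Malformed oil pools were set against normal oil pools. All 10 malformed pools were at the high level, and all 12 Lo pools were normal. The differences below may therefore follow the level as much as the malformation. The gene cyp1a, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor, rose 4.47-fold (2.16 ± 0.24 on the log2 scale, adjusted p = 1.06e-05). Its level was 5.34 ± 0.586 (SD, n = 10) in malformed and 3.18 ± 0.708 (SD, n = 14) in normal oil pools. All 10 of 10 malformed pools lay above the normal mean. The normal pools AWB_WAF_Hi 1 and CLB_WAF_Hi 3 stood at 4.28 and 4.73, and the malformed WAF Hi pools between 4.40 and 5.26. The rise was 2.62 among the arrays of scan day 1, 1.71 among those of day 2, and 2.13 with slide as a block (adjusted p = 0.00117). In the same receptor battery tiparp, a polymerase that transfers ADP-ribose and dampens the receptor, rose 1.52-fold (0.61 ± 0.09, adjusted p = 5.83e-04, 10 of 10 pools), and nqo1 did not pass (-0.14 ± 0.17). The vasoconstrictor peptide gene edn1 rose 1.61-fold (0.69 ± 0.11, adjusted p = 7.12e-04, 10 of 10 pools). The potassium channel gene kcnk6 rose by 0.62 ± 0.11 (adjusted p = 0.00189), and tmem144 rose by 1.66 ± 0.27 (0.0012). The gene fosl1, a subunit of the AP-1 transcription factor, rose by 1.04 ± 0.22 (0.0111). Each of these lay above the normal mean in 10 of 10 pools, but fosl1 lay above all normal pools in only 1. The gene gata4, a transcription factor of heart development, rose by 0.54 ± 0.13 in 10 of 10 pools (adjusted p = 0.0313). The gene sp7, the osteoblast transcription factor osterix, fell 1.48-fold (-0.57 ± 0.09, adjusted p = 0.00113, 10 of 10 pools).

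**Figure D1:**
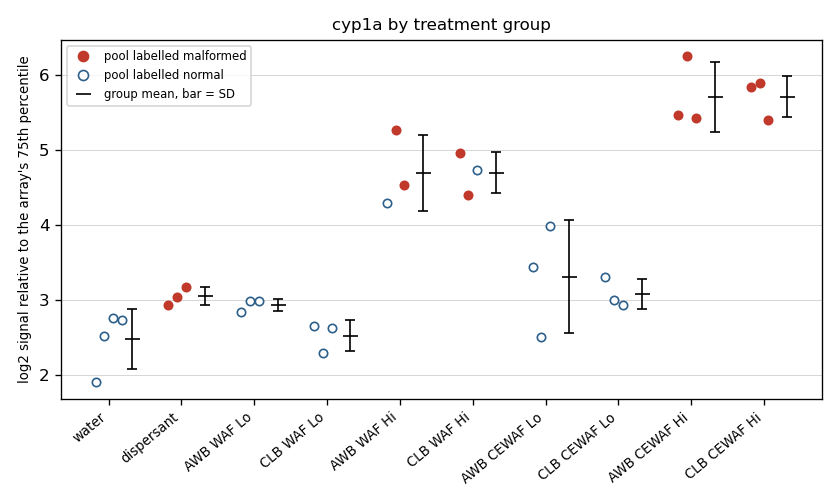
Level of cyp1a per array (log2 signal relative to the array's 75th percentile) by treatment group, with filled points for pools labelled malformed, open points for pools labelled normal, and bars for the group mean ± SD. The CEWAF Hi groups had means of 5.71 and 5.71, the WAF Hi groups 4.69 and 4.70, and water 2.47.

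Other genes of the comparison were zar1, an oocyte protein gene (0.81 ± 0.19), snx10, a sorting nexin (0.72 ± 0.15), and nt5c3a, a nucleotidase of red cells read through a cross-hybridising probe (0.59 ± 0.15), which rose (adjusted p = 0.0268, 0.0138 and 0.0404, higher in 10, 9 and 10 of 10 pools). The falls were gpr135 (-0.81 ± 0.20), pipox, a peroxisomal oxidase (-0.68 ± 0.16), otc, the urea-cycle enzyme ornithine transcarbamylase (-0.68 ± 0.14), dnph1 (-0.67 ± 0.15), psmc3ip, a recombination cofactor (-0.61 ± 0.14), pclaf, a replication clamp partner (-0.61 ± 0.16) and ebpl (-0.61 ± 0.14). Their adjusted p lay between 0.0138 and 0.0496, with 10 of 10 pools below the normal mean for each except pclaf (9 of 10). The groups overlapped, since only 0 (otc) to 7 (gpr135) of the 10 malformed pools lay below all normal pools. With slide as a block, tmem144 (adjusted p = 0.0029), edn1 (0.0169), kcnk6 (0.0122), tiparp (0.00711), gpr135 (0.0157), pipox (0.00698) and sp7 (0.0107) still passed. The calls of fosl1 (0.0582), snx10 (0.0854), otc (0.0633), gata4 (0.105), dnph1 (0.108), ebpl (0.113), nt5c3a (0.128), zar1 (0.166), pclaf (0.168) and psmc3ip (0.179) were lost. With the authors' values zar1 was at 0.25 and not called (0.0577), and fosl1 was at 0.48. The call of pclaf was lost without any 1 of 22 arrays, and those of gpr135 and nt5c3a without any 1 of 13 arrays each.

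Genes of the cell cycle and DNA replication lay lower in malformed than in normal oil pools for 26 of 26 measured members (median -0.33). Of these 0 passed over all genes and 11 fell when adjusted over the list alone, among them chaf1b (-0.55 ± 0.16), prim1 (-0.52 ± 0.15) and tk1 (-0.48 ± 0.14). The camera adjusted p was 1.04e-10, and it was adjusted p = 0.615 with an estimated correlation. The mean shift was -0.33 on scan day 1, -0.38 on day 2 and -0.33 with slide as a block. It was carried mostly by the 4 malformed WAF Hi pools, whose median difference from the normal oil pools was -0.60 (26 of 26 members lower), against -0.13 in the 6 malformed CEWAF Hi pools (19 of 26 lower). Sterol synthesis genes were lower for 11 of 14 members (median -0.37), and 7 fell when adjusted over the list alone. Among these were sqle, squalene epoxidase (-0.99 ± 0.30), and tm7sf2 (-0.54 ± 0.16). The camera adjusted p of the list was 0.00225, against adjusted p = 0.749 with an estimated correlation, and its mean shift was -0.35 on day 1, -0.27 on day 2 and -0.31 with the slide block. The median was -0.59 in the malformed WAF Hi and -0.16 in the malformed CEWAF Hi pools. Ribosomal protein genes were lower for 40 of 44 members by a median of -0.13 (camera adjusted p = 4.54e-04, adjusted p = 0.857 with an estimated correlation). Their call was lost with quantile normalisation (0.156) and normexp (0.164). Their mean shift was -0.16 on day 1, -0.07 on day 2 and -0.06 with the slide block. Their median was -0.28 in malformed CEWAF Hi and 0.09 in malformed WAF Hi pools, but most of this depended on the scaling, with -0.05, -0.04 and -0.07 in CEWAF Hi and -0.02, -0.02 and -0.03 in WAF Hi under quantile normalisation, normexp and the authors' values. Whether malformed pools of the 2 preparations differed in these lists was not tested. None of the other 21 lists tested passed. Of these, the cardiac list had a median of 0.13 (camera adjusted p = 0.128). In it gata4 rose, as did the natriuretic peptide gene nppa (0.58 ± 0.18) when adjusted over the list alone. The medians were 0.25 for retinoid and thyroid signalling (0.134), -0.13 for bone and cartilage (0.318) and -0.09 for coagulation and vascular genes (0.919, edn1 rose).

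**Figure D2:**
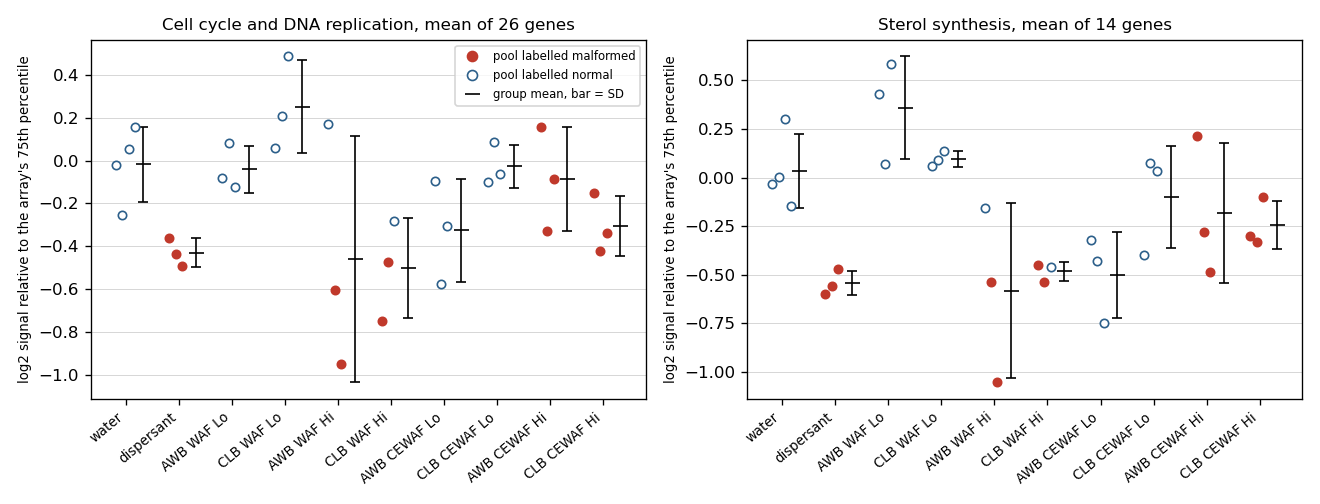
Mean level per array of the 26 cell cycle and the 14 sterol synthesis genes (log2 signal relative to the array's 75th percentile) by treatment group, with filled points for pools labelled malformed, open points for normal pools, and bars for the group mean ± SD. The cell cycle list was lower in malformed than in normal oil pools by a median of -0.33 over its 26 members (-0.60 in malformed WAF Hi and -0.13 in malformed CEWAF Hi pools).

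In all, limma called 299 of 22577 probes between malformed and normal oil pools, 159 higher and 140 lower, with 34 genes with a symbol higher and 54 lower. Of the probes, 25 changed at least 2-fold. The slide block left 119 calls, 102 of them shared with the 299. The count was 186 to 196 without AWB_WAF_Lo 1 (190), AWB_WAF_Lo 3 (186), AWB_WAF_Hi 3 (192), CLB_WAF_Hi 1 (196) or CLB_CEWAF_Lo 2 (189). It rose to 494 without CLB_CEWAF_Lo 3 and 515 without CLB_WAF_Hi 3. It was 184 without the 2 arrays least correlated with the others (AWB_WAF_Hi 3 and AWB_CEWAF_Lo 3), 24 on scan day 1 alone and 0 on scan day 2 alone (1269 at an unadjusted p under 0.05), with 5 malformed against 7 normal arrays on each day. The hatching enzyme gene hce, read through a cross-hybridising probe, was 2.95 ± 0.94 higher in malformed pools but did not pass (adjusted p = 0.111). Over its list alone it was at 0.00367, but that list holds only hce and hceb, which varied as 1 signal. Its level was 3.1 to 5.5 in malformed WAF Hi pools, but -3.1 to 3.5 in malformed CEWAF Hi pools. With hce as a covariate 48 probes were called, the cell cycle list kept its call (0.0314) and the sterol list lost it (0.31).

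The 4 water arrays serve every comparison with water below, so these comparisons are not independent of each other. Malformed oil pools had 7.30-fold more cyp1a than water (2.87 ± 0.35, adjusted p = 6.86e-05), with a water level of 2.47 ± 0.397 (SD, n = 4) and 10 of 10 malformed pools above every water pool. The difference was 3.00 on scan day 1, which held all water arrays, and 2.72 with slide as a block (adjusted p = 0.00288). No other gene with a symbol passed. The next by p were npr3, a clearance receptor for natriuretic peptides (0.50 ± 0.11, adjusted p = 0.0552), and srpx (-0.38 ± 0.09, 0.0925), each shifted in 10 of 10 pools. Cell cycle genes were lower for 26 of 26 members (median -0.39, camera adjusted p = 2.69e-11, adjusted p = 0.615 with an estimated correlation), by a mean of -0.38 on scan day 1. Their median was -0.63 in malformed WAF Hi and -0.18 in malformed CEWAF Hi pools. Sterol synthesis genes were lower for 11 of 14 members (median -0.46, 1.77e-04, adjusted p = 0.724 with an estimated correlation), and 2 fell when adjusted over the list alone. Their median was -0.70 in malformed WAF Hi and -0.19 in malformed CEWAF Hi pools, and the call was lost with hce as a covariate (0.0525). Cardiac genes were higher for 9 of 9 members (median 0.15, camera adjusted p = 0.0235, adjusted p = 0.615 with an estimated correlation), and gata4 rose when adjusted over the list alone. The cardiac call was lost with slide (0.0731), scan day (0.119) or replicate number (0.0734) as a block, without water 2 (0.094) or water 4 (0.0771), with normexp (0.0594) and with the authors' values (0.0583). In all 16 probes were called, 14 higher and 2 lower, and 3 with slide as a block. The count was 5 to 10 without water 1 (7), water 2 (6), water 3 (7), water 4 (5), AWB_WAF_Lo 3 (9), AWB_CEWAF_Hi 2 (8), CLB_CEWAF_Lo 1 (10), CLB_CEWAF_Hi 1 (8) or CLB_CEWAF_Hi 3 (9). It was 28 without CLB_WAF_Hi 2.

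No single probe passed between oil pools that were labelled normal and water (0 calls by limma, with 405 probes at an unadjusted p under 0.05 where chance gives 1129). The level of cyp1a was 0.71 ± 0.33 higher (interval 0.0287 to 1.39, adjusted p = 1, 13 of 14 pools) and 0.39 higher within scan day 1. It stood at 4.28 in AWB_WAF_Hi 1 and 4.73 in CLB_WAF_Hi 3, which belong to this group, against at most 2.75 in water. The 0 calls therefore do not show that no normal pool differed from water. The smallest p belonged to orla-uaa, a class I histocompatibility gene read through a cross-hybridising probe (0.49 ± 0.14), wisp1 (0.27 ± 0.09) and tex9 (0.36 ± 0.12), all at an adjusted p of 1 with 14 of 14 pools higher. As a group, ribosomal protein genes were higher for 42 of 44 members by a median of 0.15 (camera adjusted p = 1.11e-12, adjusted p = 0.615 with an estimated correlation), with 0 passing singly. Its mean shift was 0.16 within scan day 1 and 0.12 with slide as a block. The list passed under each scaling, but its median was only 0.04 with quantile normalisation, normexp and the authors' values.

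Dispersant alone was set against water to show the effect of the dispersant without oil. The prostacyclin synthase gene ptgis rose 3.61-fold (1.85 ± 0.32, adjusted p = 0.0128), and the transferrin gene (LOC100144362) of the liver list fell 3.18-fold (-1.67 ± 0.29, adjusted p = 0.0128). The gene gb, on a cross-hybridising probe, fell 2.25-fold (-1.17 ± 0.20, 0.0128), and efhb fell 2.07-fold (-1.05 ± 0.20, 0.0458). For each of them 3 of 3 dispersant pools lay beyond all 4 water pools. The call of efhb was lost under the 3 other scalings (0.126 to 0.16, with -0.60 at the smallest) and with slide as a random block (0.0696), and ptgis was at 1.09 with normexp and 0.99 with the authors' values. The level of cyp1a did not pass (0.57 ± 0.45, interval -0.339 to 1.49, adjusted p = 0.908, 3.05 ± 0.117 (SD, n = 3) in dispersant). Cell cycle genes were lower for 26 of 26 members (median -0.40, camera adjusted p = 1.48e-07, adjusted p = 0.743 with an estimated correlation). Sterol synthesis genes were lower for 13 of 14 (median -0.56, 6.29e-04, adjusted p = 0.743 with an estimated correlation). Adjusted over the list alone, sqle (-1.91 ± 0.55) and idi1 (-1.14 ± 0.34) fell. Neuron and glia genes were lower for 14 of 14 members (median -0.33, 0.00284, adjusted p = 0.749 with an estimated correlation). Immune genes were higher for 11 of 15 (median 0.21, 0.0447, adjusted p = 0.615 with an estimated correlation). Adjusted over the list alone, stat3 (0.58) and the collagenase gene coll (1.62) rose. The neuron call was lost with slide as a block (0.116) and without water 2 (0.0985) or dispersant 2 (0.0935). The immune call was lost with slide (0.409), scan day (0.314) or replicate number (0.0942) as a block, with normexp (0.0785) and with the authors' values (0.064). It was also lost without water 2 (0.0899), water 4 (0.103), dispersant 1 (0.085), dispersant 3 (0.122), AWB_CEWAF_Hi 3 (0.0509), CLB_WAF_Lo 2 (0.0501) or CLB_CEWAF_Hi 3 (0.0527).

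In all 9 probes were called between dispersant and water, 5 higher and 4 lower (55.6% higher, against 66.7% with quantile normalisation and 70% with normexp or the authors' values). The hce level was 4.78 ± 1.73 higher in dispersant but did not pass (adjusted p = 0.579, and 0.011 over the list of hce and hceb alone). With it as a covariate the cell cycle (0.803), sterol (0.462) and immune (0.361) calls were lost. No slide and no scan day held both controls, so batch and treatment cannot be told apart directly for this comparison. By limma 0 probes were called with slide, scan day or replicate number as a block (1583, 1227 and 911 at an unadjusted p under 0.05). The count fell to 0 without water 1, water 3, water 4, dispersant 1 or dispersant 2 (892 to 1671 at an unadjusted p under 0.05), which also ended the calls of ptgis, transferrin and gb. It fell to 5 without water 2, AWB_WAF_Lo 2, AWB_CEWAF_Lo 3, CLB_WAF_Lo 1, CLB_WAF_Lo 2, CLB_WAF_Lo 3 or CLB_CEWAF_Lo 1.

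Malformed oil pools and dispersant pools share the malformed label and differ in the oil. They also differ in other ways, since the 4 malformed WAF Hi pools had no dispersant, and all dispersant arrays lay on scan day 2 but only 5 of the 10 malformed oil arrays. Between them cyp1a was 4.90-fold higher with oil (2.29 ± 0.39, adjusted p = 0.0182), edn1 1.86-fold (0.90 ± 0.17, 0.0436) and gb 1.87-fold (0.90 ± 0.17, 0.0436), each with 10 of 10 oil pools above all 3 dispersant pools. The call of cyp1a was lost without dispersant 1, 2 or 3, that of gb without any 1 of 21 arrays and that of edn1 without any 1 of 18. In all 9 probes were called, 8 higher and 1 lower (88.9% higher, against 60.0% with the authors' values and 58.8% with normexp), and 0 with slide as a block (1602 at an unadjusted p under 0.05). Without dispersant 3 the direction turned, with 3 calls that were all lower and only 1 of them shared with the 9. The count fell to 0 without dispersant 1 or 2 (1174 and 1366), to 3, all higher, without AWB_CEWAF_Hi 1, AWB_CEWAF_Hi 3 or CLB_WAF_Hi 1, and to 5 without CLB_CEWAF_Hi 3. It was 2 without water 1, water 4, AWB_WAF_Lo 1, AWB_WAF_Lo 2, AWB_WAF_Lo 3, AWB_CEWAF_Lo 1, CLB_WAF_Lo 1, CLB_WAF_Lo 3, CLB_CEWAF_Lo 1, CLB_CEWAF_Lo 2 or CLB_CEWAF_Hi 1, and 20 without CLB_WAF_Hi 2.

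Each preparation and level was also set against water, with both oils together. At the low level no probe passed. For WAF Lo, cyp1a was 0.25 ± 0.24 higher (interval -0.239 to 0.746, adjusted p = 1, 5 of 6 pools), and for CEWAF Lo 0.72 ± 0.24 (interval 0.226 to 1.21, adjusted p = 1, 6 of 6 pools). The smallest p for WAF Lo belonged to plau, the urokinase gene (0.70 ± 0.21), wisp1 (0.28 ± 0.09) and med24 (0.32 ± 0.10, cross-hybridising), all at an adjusted p of 1 and higher in 6 of 6 pools. For CEWAF Lo they belonged to arhgef25 (0.74 ± 0.17, adjusted p = 0.627), mnep (-0.90 ± 0.26, cross-hybridising) and inip (-0.42 ± 0.12), the last pair at an adjusted p of 1, each shifted in 6 of 6 pools. The calls by limma were 0 and 0, with 452 and 1039 probes at an unadjusted p under 0.05 where chance gives 1129. For CEWAF Lo 1 probe was called without AWB_CEWAF_Lo 1 or CLB_CEWAF_Hi 2.

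At the high level of WAF, cyp1a rose 4.66-fold over water (2.22 ± 0.24, adjusted p = 4.38e-05), with 6 of 6 pools above all water pools. It was 2.63 higher within scan day 1 and 2.29 with slide as a block (0.00137). The heart transcription factor hand1 rose 1.48-fold (0.57 ± 0.11, adjusted p = 0.0375), and spsb3 fell 2.33-fold (-1.22 ± 0.23, 0.04), each in 6 of 6 pools. The call of hand1 held with slide as a fixed (0.0464) or random block (0.017) and under the other 3 scalings. It was lost with the replicate block (0.0729), scan day as a block (0.163), hce as a covariate (0.999), scan day 1 alone (0.138), the compared arrays alone (0.997) and without the 2 least correlated arrays (0.103). The call of spsb3 was lost with slide as a fixed block (0.0679), the replicate block (0.173), scan day as a block (0.155), hce (0.999), the compared arrays alone (0.997), without the 2 least correlated arrays (0.103) and under the other 3 scalings. Its difference was only -0.62 with normexp and -0.54 with the authors' values. Leaving out any 1 of 15 arrays ended the call of hand1, and any 1 of 18 that of spsb3. When adjusted over the list alone, 7 sterol synthesis genes fell and 1 rose (ebp -1.30 ± 0.31, sqle -1.50 ± 0.38), and 8 cell cycle genes fell (tyms -0.85 ± 0.23). In the same way the liver enzymes tdo2 (-1.14) and tat (-0.93) fell. In all 13 probes were called, 9 higher and 4 lower (69.2% higher, 85.7% with quantile normalisation), and with slide as a block 73, 8 of them shared with the 13. The excess of rises did not hold throughout, with 23 higher and 50 lower for slide as a fixed block, 37 and 50 for slide as a random block, and 70 and 86 on scan day 1 alone. The count was 1 without water 1, water 3, water 4 or AWB_WAF_Hi 3, 2 without water 2, dispersant 2 or AWB_WAF_Hi 2, and 4 without AWB_WAF_Lo 2 or CLB_WAF_Hi 1. It was 6 without dispersant 1, 7 without dispersant 3, AWB_WAF_Lo 3 or CLB_WAF_Hi 2, and 8 without CLB_WAF_Lo 2 or CLB_WAF_Lo 3. It rose to 230 without CLB_WAF_Hi 3 (97 higher and 133 lower), to 572 without AWB_WAF_Hi 1 (219 and 353), and to 1175 without both (469 and 706), which are the 2 WAF Hi pools labelled normal.

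At the high level of CEWAF, cyp1a rose 9.42-fold over water (3.24 ± 0.24, adjusted p = 5.3e-09, 3.25 within scan day 1, 3.29 with slide as a block, 4.52e-07). The steroid- and drug-metabolising cytochrome gene cyp3a40 rose 2.34-fold (1.23 ± 0.23, adjusted p = 0.0102, 0.00722 with slide as a block) and c1qtnf7, a secreted protein related to complement C1q, 2.16-fold (1.11 ± 0.17, 0.00162, block 0.00137). The dehydrogenase gene dhrs13 rose by 1.20 ± 0.27 (adjusted p = 0.0464, block 0.119) and nkd1, an inhibitor of Wnt signalling, by 1.33 ± 0.29 (0.0415, block 0.0779). The gene nkd1 was dim in 2 of the 4 water pools, and its difference was 0.14 at the lowest among the scalings. The falls were srpx (-0.45 ± 0.10, adjusted p = 0.0358, block 0.0637, normexp 0.0616) and snai2, a transcription factor of mesenchymal cells (-0.38 ± 0.09, 0.0481, block 0.0737). For each of these genes 6 of 6 pools lay beyond all 4 water pools. The calls of cyp1a and c1qtnf7 held whichever array was left out, and that of cyp3a40 was lost without water 2 or water 4. Those of nkd1, dhrs13, srpx and snai2 were lost without any 1 of 15, 23, 9 and 27 arrays. The receptor target tiparp rose as well (0.67 ± 0.15, adjusted p = 0.0481). Adjusted over the list alone, nppa rose (0.84 ± 0.22), and 5 genes of bone and cartilage fell while 1 rose. In all 77 probes were called, 62 higher and 15 lower, and with slide as a block 93, of which 49 were shared. The count was 35 without water 1, 35 without water 2, 41 without water 3 and 47 without CLB_CEWAF_Hi 3.

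The high level was set against the low level over both oils and both preparations. In this comparison cyp1a rose 4.73-fold (2.24 ± 0.15, adjusted p = 2.95e-09), with 12 of 12 Hi pools above all 12 Lo pools, by 2.62 on scan day 1, 1.91 on day 2 and 2.35 with slide as a block (1.61e-06). The rises that followed were tmem144 (1.56 ± 0.29, adjusted p = 0.0078, 11 of 12 pools), fosl1 (1.13 ± 0.20, 0.00564, 11 of 12), prrg4 (0.74 ± 0.18, 0.0396, 10 of 12) and prdm1b, a transcription factor of cell fate (0.72 ± 0.10, 1.63e-04, 12 of 12). The gene sqle fell 2.17-fold (-1.12 ± 0.24, adjusted p = 0.019, 11 of 12), and otc (-0.80 ± 0.12, 8.15e-04, 12 of 12), katnal2 (-0.77 ± 0.15, 0.0129, 12 of 12), pld4 (-0.76 ± 0.19, 0.0461, 11 of 12) and dnph1 (-0.62 ± 0.14, 0.0274, 11 of 12) fell too. The slide block ended the calls of prrg4 (0.23) and pld4 (0.398), and normexp and the authors' values those of katnal2 and pld4, the latter also with quantile normalisation. With normexp and the authors' values katnal2 was at only -0.165 and -0.111, and pld4 at -0.43 and -0.39. Leaving out any 1 of 17 arrays ended the call of prrg4, any 1 of 23 that of pld4 and any 1 of 9 that of dnph1. From the lists, gata4 (0.58 ± 0.13), nppa (0.61 ± 0.14), edn1 (0.63 ± 0.11), angpt2 (0.59 ± 0.12), tiparp (0.47 ± 0.09) and cyp3a40 (0.65 ± 0.14) rose, and sp7 fell (-0.46 ± 0.10), with adjusted p from 0.00616 to 0.0291.

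Cell cycle genes were lower at the high level for 26 of 26 members (median -0.25, camera adjusted p = 1.73e-08, adjusted p = 0.73 with an estimated correlation), and 6 fell when adjusted over the list alone. The mean shift was -0.33 on day 1, -0.31 on day 2 and -0.39 with the slide block. The fall was seen in WAF, with a median of -0.56 between Hi and Lo (25 of 26 members lower), whereas in CEWAF it was -0.04 (15 of 26 lower). Sterol synthesis genes were lower for 11 of 14 (median -0.30, 1.98e-04, adjusted p = 0.615 with an estimated correlation), by a mean of -0.35 on each scan day and -0.54 with the slide block. With sqle, 6 members fell when adjusted over the list alone. Their median between Hi and Lo was -0.81 in WAF (13 of 14 lower) and 0.02 in CEWAF (7 of 14 lower). The mean level of the sterol list was -0.30 in CEWAF Lo, -0.21 in CEWAF Hi, 0.23 in WAF Lo and 0.03 in water, and that of the cell cycle list -0.18, -0.20, 0.10 and -0.02. The CEWAF Lo pools were uneven, from -0.75 to 0.07 for the sterol and from -0.57 to 0.09 for the cell cycle list, and neither list was tested between CEWAF Lo and water. Ribosomal protein genes were lower for 38 of 44 (median -0.12, 1.50e-04, adjusted p = 0.822 with an estimated correlation), a call lost with quantile normalisation (0.281) and normexp (0.343). Their median was -0.27 in CEWAF and 0.04 in WAF, but -0.03 to -0.05 in CEWAF and below 0 in WAF under the 3 other scalings. The lens crystallin genes were lower for 6 of 6 (median -0.31, 0.0325, adjusted p = 0.822 with an estimated correlation), by -0.08 on day 1 and -0.50 on day 2. Their median was -0.57 in CEWAF and -0.02 in WAF. By the interaction, adjusted over the list alone, the effect of the level differed between the preparations for 8 cell cycle and 11 sterol genes and for no ribosomal or lens gene. The lens call was lost with slide as a block (0.223) and without AWB_WAF_Hi 1 (0.119), AWB_CEWAF_Lo 3 (0.0941), AWB_CEWAF_Hi 1 (0.0631), CLB_WAF_Lo 2 (0.0903), CLB_WAF_Lo 3 (0.0542), CLB_WAF_Hi 3 (0.161), CLB_CEWAF_Lo 1 (0.0572) or CLB_CEWAF_Hi 3 (0.0527). In all 321 probes were called, 213 higher and 108 lower, and with slide as a block 199 (106 higher and 93 lower), of which 119 were shared. The count was 143 to 213 without AWB_WAF_Lo 1 (174), AWB_WAF_Lo 3 (213), AWB_WAF_Hi 2 (177), AWB_WAF_Hi 3 (199), AWB_CEWAF_Hi 1 (180), CLB_WAF_Lo 2 (193), CLB_WAF_Lo 3 (188), CLB_CEWAF_Lo 1 (143), CLB_CEWAF_Lo 2 (161), CLB_CEWAF_Hi 2 (151) or CLB_CEWAF_Hi 3 (182). It was 969 without AWB_WAF_Hi 1 (487 higher and 482 lower), 613 without CLB_CEWAF_Lo 3, and 1106 without the 2 normal WAF Hi pools (510 and 596). On scan day 1 alone 48 probes were called and on day 2 alone 2. With hce as a covariate 30 were called, and the cell cycle call was lost (0.148).

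The preparation with dispersant was set against the one without, over both oils and levels. The gene notum, an enzyme that inactivates Wnt proteins, rose 1.64-fold (0.71 ± 0.11, adjusted p = 0.00617, 12 of 12 pools, 0.65 on scan day 1, 0.81 on day 2, block 0.011), and fjx1 rose by 0.45 ± 0.10 (0.0419, 11 of 12, block 0.136). The gene cyp1a rose 1.67-fold (0.74 ± 0.15, 0.0349, 7 of 12 pools above the WAF mean, 0.60 and 1.01 by day, block 0.0407). The falls were fgfbp2 (-0.62 ± 0.14, adjusted p = 0.0482, 11 of 12), hyi (-0.50 ± 0.10, 0.0348, 12 of 12) and gatm, an enzyme of creatine synthesis (-0.48 ± 0.10, 0.031, 12 of 12). Also lower were cltrn, collectrin (-0.47 ± 0.10, 0.0348, 12 of 12, block 0.0397) and tmem45a (-0.41 ± 0.09, 0.0479, 11 of 12). Apart from cyp1a, notum and cltrn, these calls were lost with slide as a block, and the replicate block ended those of cyp1a (0.055) and cltrn (0.0508) too. The calls of fgfbp2 and gatm were lost under the 3 other scalings (0.0674 to 0.0999), and that of tmem45a with quantile normalisation (0.0616). Without any 1 of 13 arrays cyp1a was not called, whereas notum was called in each fit that left out 1 array and under each scaling, at 0.40 with the authors' values. The calls of fjx1, fgfbp2, hyi, gatm, cltrn and tmem45a were lost without any 1 of 10 to 24 arrays. Ribosomal protein genes were lower with CEWAF for 42 of 44 members (median -0.19, camera adjusted p = 9.71e-12, adjusted p = 0.615 with an estimated correlation). The call was lost with quantile normalisation (0.12), normexp (0.151) and the authors' values (0.136). Adjusted over the list alone, rpl37 (-0.30) and rpl29 (-0.24) fell. Photoreceptor genes were lower for 12 of 15 (median -0.21, 4.99e-04, adjusted p = 0.724 with an estimated correlation). Their mean shift was -0.28 on day 1, -0.20 on day 2 and -0.28 with the slide block, and the call was lost under the 3 other scalings (0.069 to 0.0962). Of these rho, rhodopsin (-0.25 ± 0.06), guca1a (-0.39) and rdh5 (-1.10) were among 6 that fell when adjusted over the list alone.

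Extracellular matrix genes were lower with CEWAF for 9 of 10 members (median -0.19, camera adjusted p = 0.00678, adjusted p = 0.615 with an estimated correlation). The mean shift was -0.15 on each day and with the slide block, and 5 fell when adjusted over the list alone (vim -0.43, dcn, tgfbi, col4a1 and fn1). Genes of the mitochondrial respiratory chain were lower for 15 of 17 (median -0.09, 0.0325, adjusted p = 0.822 with an estimated correlation), but the direction turned with quantile normalisation (0.818), normexp (0.893) and the authors' values (0.765). With the slide block the call was lost (0.0914). It was also lost without AWB_WAF_Lo 2 (0.0783), AWB_WAF_Hi 1 (0.107), AWB_CEWAF_Hi 3 (0.0653), CLB_WAF_Lo 2 (0.0697), CLB_WAF_Hi 2 (0.187), CLB_CEWAF_Lo 3 (0.0937) or CLB_CEWAF_Hi 3 (0.114). In all 70 probes were called between the preparations, 31 higher and 39 lower, and with slide as a block 41 (24 higher and 17 lower), of which 28 were shared. More probes were higher than lower under the 3 other scalings too (36 and 34 with normexp). The count was 14 to 44 without water 1 (37), dispersant 2 (42), AWB_WAF_Lo 1 (37), AWB_WAF_Lo 2 (27), AWB_WAF_Lo 3 (19), AWB_WAF_Hi 2 (23), AWB_CEWAF_Lo 1 (20), AWB_CEWAF_Lo 2 (44), AWB_CEWAF_Lo 3 (28), AWB_CEWAF_Hi 3 (23), CLB_WAF_Lo 2 (27), CLB_WAF_Lo 3 (25), CLB_WAF_Hi 2 (17), CLB_CEWAF_Lo 1 (28), CLB_CEWAF_Lo 2 (14), CLB_CEWAF_Hi 2 (22) or CLB_CEWAF_Hi 3 (37). It was 320 without CLB_WAF_Hi 3.

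Between the oils, AWB and CLB, limma called 0 probes, with 1678 at an unadjusted p under 0.05 where chance gives 1129. The difference in cyp1a was 0.16 ± 0.15 (interval -0.152 to 0.47, adjusted p = 0.891, 6 of 12 AWB pools above the CLB mean). The smallest p belonged to zbtb49 (0.53 ± 0.11, adjusted p = 0.333, 10 of 12), scarb1, a receptor for high-density lipoprotein (-0.43 ± 0.10, 0.372, 12 of 12) and zc3hc1 (0.29 ± 0.07, 0.387, 12 of 12). Neuron and glia genes were higher with AWB for 12 of 14 members (median 0.12, camera adjusted p = 0.00899, adjusted p = 0.822 with an estimated correlation), by a mean of 0.19 on scan day 1, 0.09 on day 2 and 0.19 with the slide block. Their call was lost without AWB_WAF_Hi 3 (0.0619), AWB_CEWAF_Hi 3 (0.0934) or CLB_CEWAF_Hi 1 (0.063). Ribosomal protein genes were higher with AWB for 36 of 44 (median 0.15, 2.36e-10, adjusted p = 0.615 with an estimated correlation), but the call was lost with quantile normalisation (0.73) and normexp (0.758), and the direction turned with the authors' values (0.979).

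Whether the effect of the level depended on the preparation was tested as an interaction. The gene ebp, a sterol isomerase, had a log2 difference of Hi from Lo that was 2.04 ± 0.39 higher with CEWAF than with WAF (adjusted p = 0.0223). Its level went from 0.65 and 0.48 (AWB and CLB) at WAF Lo to -1.21 and -1.06 at WAF Hi, and from -0.93 and -0.35 at CEWAF Lo to -0.31 and -0.30 at CEWAF Hi, against 0.16 in water and -0.77 in dispersant. The same term was 1.72 ± 0.34 for dhrs13 (0.0243), 1.49 ± 0.29 for cyp3a40 (0.0223), 1.097 ± 0.22 for c1qtnf7 (0.0266), 1.00 ± 0.21 for pttg1, securin (0.0356), and -0.83 ± 0.18 for the chemokine gene cxcl12 (0.0476). The cyp3a40 level was 3.93 and 4.42 in CEWAF Hi, 2.81 and 3.06 in WAF Hi, 2.95 in water and 4.11 in dispersant. When slide was a block, the calls of ebp and cyp3a40 held and the other 4 were lost. The term of pttg1 was 0.59 with normexp and 0.55 with the authors' values. The call of pttg1 was lost under the 3 other scalings (0.0872 to 0.109) and that of c1qtnf7 with quantile normalisation (0.0909), and cxcl12 was at -0.34 with the authors' values. That of cyp3a40 was lost without AWB_WAF_Lo 3 or AWB_CEWAF_Hi 1, and those of ebp, dhrs13, c1qtnf7, pttg1 and cxcl12 without any 1 of 4, 6, 12, 19 and 22 arrays. For cyp1a the term did not pass (0.55 ± 0.30, interval -0.0718 to 1.17, adjusted p = 0.456). Adjusted over the list alone, the term was higher with CEWAF for 11 sterol synthesis genes, 8 cell cycle genes and 7 genes of fatty acid and lipid metabolism, among them plk1 (0.89), elovl5 (1.85) and lipc (2.86). In all 66 probes were called, 60 higher and 6 lower, and with slide as a block 35, of which 28 were shared.

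**Figure D3:**
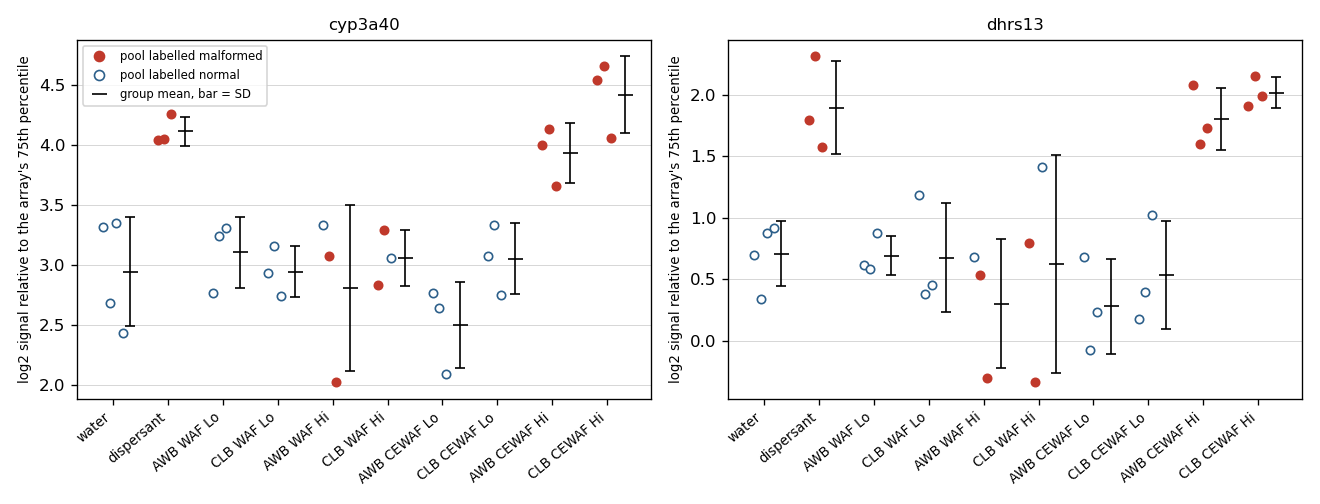
Levels of cyp3a40 and dhrs13 per array (log2 signal relative to the array's 75th percentile) by treatment group, with filled points for pools labelled malformed, open points for normal pools, and bars for the group mean ± SD. The cyp3a40 mean was 4.11 in dispersant, 3.93 and 4.42 in the CEWAF Hi groups and 2.95 in water.

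The interaction count was 25 to 42 without AWB_WAF_Lo 1 (37), AWB_WAF_Lo 2 (34), AWB_WAF_Lo 3 (29), AWB_WAF_Hi 2 (30), AWB_WAF_Hi 3 (34), AWB_CEWAF_Lo 2 (30), AWB_CEWAF_Lo 3 (38), AWB_CEWAF_Hi 1 (25), CLB_WAF_Lo 1 (31), CLB_WAF_Lo 3 (28), CLB_WAF_Hi 1 (38), CLB_WAF_Hi 2 (39), CLB_CEWAF_Lo 1 (31), CLB_CEWAF_Lo 3 (42), CLB_CEWAF_Hi 1 (36), CLB_CEWAF_Hi 2 (41) or CLB_CEWAF_Hi 3 (31). It was 804 without CLB_WAF_Hi 3, 633 without AWB_WAF_Hi 1 and 121 without AWB_CEWAF_Lo 1. It was 4 with hce as a covariate, 0 on scan day 1 alone (2182 at an unadjusted p under 0.05) and 1 on scan day 2 alone. For the interaction of the level with the oil, limma called 0 probes, with 1357 at an unadjusted p under 0.05, and 1 without AWB_WAF_Lo 2, AWB_CEWAF_Lo 1, AWB_CEWAF_Hi 3 or CLB_WAF_Hi 3. The smallest p belonged to the splicing gene usp39 (0.70 ± 0.15, adjusted p = 0.366), the mitochondrial chaperone hspd1 (0.81 ± 0.18, 0.413) and pcbd2 (-1.54 ± 0.36, 0.51), and cyp1a differed by -0.32 ± 0.30 (0.885). Adjusted over the list alone, this term passed for the lens genes cryaa (-1.26) and crybb1 (-1.07).

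Within WAF Hi, where level and preparation were the same, the 4 malformed pools were set against the 2 normal ones. The hepatic lipase gene lipc fell 8.22-fold in the malformed pools (-3.04 ± 0.52, adjusted p = 0.00421), with a level of -3.85 ± 0.458 (SD, n = 4) against -0.81 ± 0.0307 (SD, n = 2). The liver enzymes tdo2 (-1.77 ± 0.28, adjusted p = 0.00347) and tat (-1.55 ± 0.29, 0.00852) fell. So did gda, guanine deaminase (-2.19 ± 0.42, 0.00967), and plb1, a phospholipase (-2.17 ± 0.37, 0.00454). The cytochrome gene cyp2p3 was lower as well (adjusted p = 0.0228, 0.059 with slide as a block), but its signal in AWB_WAF_Hi 3 was not well above background. The size of its difference is therefore uncertain, at -3.45 ± 0.78 here, -1.80 with normexp and -1.63 with the authors' values. The gene noxo1, an organiser of NADPH oxidase, was at -2.70 ± 0.70 (0.0442), but at -1.36 and no longer called with the authors' values (0.0514), and not called with slide (0.126) or replicate number (0.0818) as a block. The rises were proca1 (1.21 ± 0.19, adjusted p = 0.00354), snx10 (1.18 ± 0.20, 0.00421), sh3d21 (1.01 ± 0.19, 0.00852), the pigmentation gene oca2 on a cross-hybridising probe (1.00 ± 0.21, 0.0151, but 0.058 with normexp and 0.0612 with the authors' values) and the potassium channel gene kcnj8 (0.97 ± 0.20, 0.0165). Each of the 10 largest changes lay in 4 of 4 malformed pools beyond both normal pools. Of the cell cycle list 5 genes fell (gins1 -0.97 ± 0.22, adjusted p = 0.0242, tk1, tyms, rfc4 and smc2), and 12 when adjusted over the list alone. Adjusted in the same way, 6 lens genes rose (lgsn 1.03, cryaa 0.76), 4 sterol genes fell, and the chaperones hspa5 (1.75 ± 0.48) and dnajb9 (0.99) rose. The level of cyp1a did not differ by the test (0.28 ± 0.32, interval -0.386 to 0.942, adjusted p = 0.809), and stood at 4.28 and 4.73 in the 2 normal pools.

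In all 447 probes were called within WAF Hi, 98 higher and 349 lower, with 18 genes with a symbol higher and 87 lower. The slide block left 160, 128 of them shared, and the calls of lipc, snx10, sh3d21, kcnj8, gda and plb1 held. The count was 3 without AWB_WAF_Hi 1, 149 without AWB_WAF_Hi 3, 278 without CLB_WAF_Hi 2 and 273 without CLB_WAF_Hi 3. Without CLB_WAF_Hi 3 the excess of falls was gone (133 higher and 140 lower). Where 1 normal pool was left out, the remaining one was assumed to vary like the other groups. With 2 pools on one side the recovery on simulated data was low (35.8% at 2-fold), and a fit to the 6 arrays alone called 22 (10 higher and 12 lower). The hce level was 4.12 ± 1.74 higher in the malformed pools but did not pass (adjusted p = 0.276, and 0.0276 over the list of hce and hceb alone). With it as a covariate 44 probes were called.

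**Figure D4:**
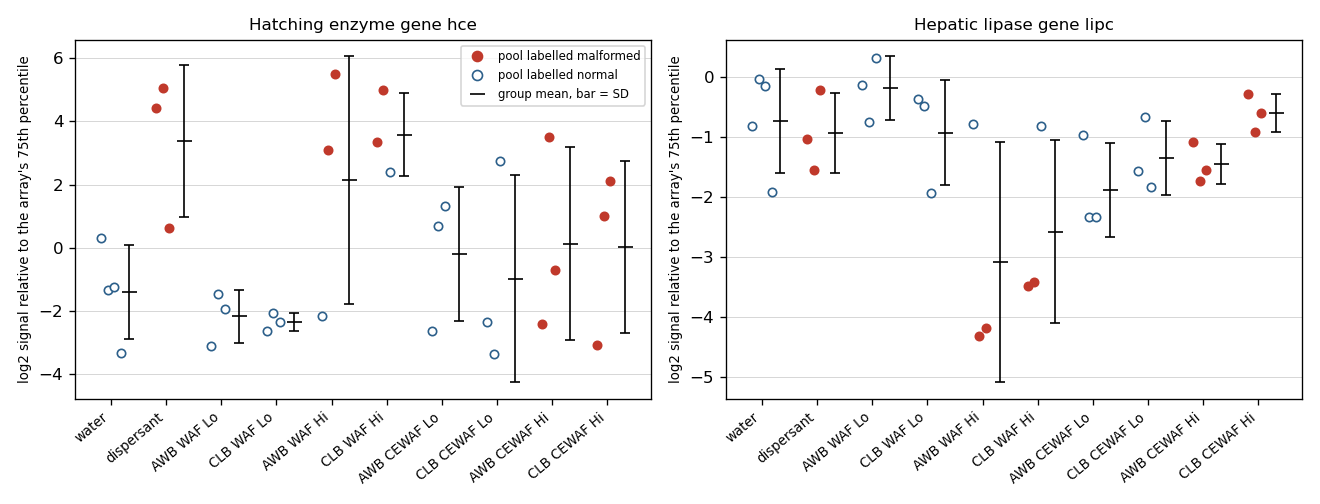
Level of the hatching enzyme gene hce and of the liver lipase gene lipc per array (log2 signal relative to the array's 75th percentile) by treatment group, with filled points for pools labelled malformed, open points for normal pools, and bars for the group mean ± SD. Over the arrays hce ranged from -3.38 to 5.50.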

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

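Among the tests of this part, that of slide differences within WAF Hi was chosen only after its result was seen. The fits without selected arrays and those with hce as a covariate or scan day as a block were also chosen after the data were seen. For exposure level alone, 1 condition for reading the test was added after its value was known, as stated with it. The comparison of scalings for the ribosomal genes was also added after the first value was known. For the unusual pool, the number of other choices was first expected to be 29 and was 23, and the wording of that test was changed to fit.

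In the malformed oil pools, gata4 stood apart in AWB_WAF_Hi 3, at -0.0498, where the other 9 pools lay between -1.13 and -0.554. It was the only sample far from the rest of its group among 53 groups of 4 to 10 samples that were looked at for the named genes, where chance alone gives about 1 in 20 groups, or 2.6. The effect of the high level differed between the preparations for 66 probes by the interaction test, and for the genes ebp (2.04), dhrs13 (1.72), cyp3a40 (1.49), c1qtnf7 (1.097), pttg1 (1.00) and cxcl12 (-0.83). No biological explanation was tested for these beyond the comparison with dispersant under the other observations.

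The first pattern weighed is the set of 299 probes between malformed and normal oil pools. Against slide or scan day as the whole cause, 99% of the 200 probes with the smallest p on scan day 1 had the same direction on scan day 2, whose arrays lay on other slides. In reverse, 91.5% of the 200 top probes of day 2 had the same direction on day 1. Over all probes the share was 64.47%. Level and phenotype cannot be told apart, because the 2 WAF Hi pools labelled normal gave mixed values. On probes that mark CEWAF Hi, the higher of them exceeded the lowest malformed WAF Hi pool by 0.751, which by the rule as first written favoured the level alone. The test decides nothing, because the malformed WAF Hi pools themselves were not raised on these probes (mean -0.107), a condition added after the value was seen. On scores from probes chosen without the scored pool (0 for the Lo mean, 1 for the malformed mean), AWB_WAF_Hi 1 stood at 0.145 and CLB_WAF_Hi 3 at 0.751, against at most 0.543 in Lo pools and at least 0.541 in malformed pools. The lower of them lay -0.398 from the highest Lo pool. Since the 2 classes overlapped on this score and the 2 pools fell apart, it does not show whether either followed its phenotype or its level.

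The second pattern is the set of 447 probes within WAF Hi, where the liver genes lipc, tdo2 and tat fell and cell cycle genes fell in the malformed pools. Slide differences as the whole cause are not settled by the slide block, which left 96.9% of the median difference but fewer calls. An effect of the single pool AWB_WAF_Hi 1 stays open, since 66.3% of the probes called in the AWB pools alone had the same direction in the CLB pools. Without that pool, which leaves only the CLB pools, 3 probes were called, and each fit to 1 oil had a single normal pool that was assumed to vary like the other groups. In addition 2 of 23 other choices of 1 array gave as large a mean as CLB_WAF_Hi 3 (0.304). Both lay on the slide of AWB_WAF_Hi 1. They were AWB_CEWAF_Hi 1 (0.354) and dispersant 1 (0.305), whereas CLB_WAF_Hi 2 on that slide was at 0.0091. A difference of that slide therefore stays open as well. A candidate explanation is that the malformed pools differed in their stage around hatching, since 83.9% of the 447 probes varied with hce in the direction of their difference over the 25 arrays outside WAF Hi, against 52.9% of all probes, and 44 probes were called with hce as a covariate. Malformation itself, which may also delay hatching, was not separable from the stage in these arrays.

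The third pattern is the higher level of ribosomal protein genes in normal oil pools than in water. A scaling effect on bright probes stays open. The list's median exceeded that of 224 genes matched for brightness by 0.121 on the log2 scale, but by only 0.048 with quantile normalisation, 0.0357 with normexp and 0.039 with the authors' values. Slide differences as the whole cause are argued against by the values within slides. There the normal oil arrays lay above the water array by 0.164 on average, against 0.1622 over all arrays. The test as set stayed undecided, because the excess was only 0.0262 on slide 1, and each slide held a single water array. An effect of the oil is the biological explanation the design offers, and it remains untested apart from these values.

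Other splits of the same samples into groups of the same sizes were fitted, up to 100 per comparison with the real split included. A count this large by chance can be excluded at 5% for malformed against normal oil (2 of 100 splits gave as many as 299, the highest other 2671), CEWAF Hi against water (1 of 100, 77 against 1), Hi against Lo (2 of 100, 321 against 2154), CEWAF against WAF (1 of 100, 70 against 7) and the interaction of level with preparation (1 of 100, 66 against 2). For dispersant against water 1 of 35 splits gave as many (9 against 2). That real split is also the split by scan day, so only a grouping unrelated to batch is excluded, and limma called 0 probes with slide, scan day or replicate number as a block (1583, 1227 and 911 at an unadjusted p under 0.05). Chance cannot be excluded for malformed oil against water (8 of 100, 16 against 608), malformed oil against dispersant (7 of 100, 9 against 858) or WAF Hi against water (7 of 100, 13 against 397). The comparisons with 0 calls gave 100 of 100 by their nature, with highest other counts of 1 for normal oil against water, 1 for WAF Lo, 2 for CEWAF Lo, 3 for AWB against CLB and 149 for the interaction of level with oil. Splits with several times the real count point to a structure of the samples. The splits with 2671 and 2154 calls parted the arrays along the largest component of variation (by -0.894 and -1.31 SD, against -0.0305 and -0.189 for the real splits), which followed the slide, and with slide as a block the real splits gave 119 and 199 probes. Some other splits went with hce. For WAF Hi against water, those with 193, 155 and 134 calls differed in hce by 4.61, 4.65 and 5.30, among the 4 largest of 100, and the real split by 4.27. The splits of that comparison with 397, 112 and 19 calls differed less in hce (-0.0919, 2.71 and 0.59). They parted the arrays more along the component (1.79, -1.25 and -1.46 SD). The splits with 608 and 858 calls differed both in hce (-3.14 and -3.26) and along the component (0.755 and 0.809 SD).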

How the results depend on the processing

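Of the settings below, those with scan day, hce, the least correlated arrays and the normal WAF Hi pools were chosen after the data were seen, and the others were planned. With quantile normalisation, without a filter on dim probes and with the stricter filter, the counts of all comparisons stayed within 1.5 times those reported. The count of normal oil against water was 0 in each setting that gave a value. Of the 21 gene list calls, quantile normalisation kept 15, normexp 13, the authors' values 15, the slide block 16, the replicate block 19, scan day as a block 19, hce as a covariate 15, and the fit to the compared arrays and the mean over probes 21. The named genes made 70 calls, where a gene counts once for each comparison in which it passed, so that cyp1a counts several times. Of these calls, quantile normalisation kept 61, normexp 60, the authors' values 58, the stricter filter 70, no filter 69, the slide block 33 and slide as a random block 66. The replicate block kept 49, the compared arrays alone 30, scan day as a block 48, the fit without the least correlated arrays 47 and hce as a covariate 29. Scan day 1 alone kept 13 of the 53 that could be tested there, and scan day 2 alone 1 of 55. For the list calls these were 14 of 17 and 7 of 13. Dim signal limits genes such as zar1, nkd1, katnal2 and cyp2p3, which were not well above background on every array. Where a value changed below, the cause was not tested, except that a higher threshold leaves fewer calls by construction.

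With normexp, the counts rose to 505 for malformed against normal oil, 17 for malformed oil against dispersant, 23 for WAF Hi against water, 119 for CEWAF Hi against water and 560 for Hi against Lo, and 13 lists were called. With the authors' values they were 511 for malformed against normal oil, 15 for malformed oil against dispersant, 22 for WAF Hi and 562 for Hi against Lo. The mitochondrial list turned direction between CEWAF and WAF (adjusted p = 0.818 with quantile normalisation, 0.893 with normexp, 0.765 with the authors' values), as did the ribosomal list between AWB and CLB with the authors' values (0.979). With a correlation estimated per list, and with fry, 0 lists passed.

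With slide as a fixed block, the counts were 119 for malformed against normal oil, 3 for malformed oil against water, 0 for dispersant against water and 0 for malformed oil against dispersant. They were 73 for WAF Hi, 199 for Hi against Lo, 41 for CEWAF against WAF, 35 for the interaction with preparation, 1 for the interaction with oil and 160 within WAF Hi. With slide as a random block they were 87 for WAF Hi, 1 for CEWAF Lo, 145 for CEWAF Hi, 175 for CEWAF against WAF, 1 for AWB against CLB, 250 for the interaction with preparation and 1 for that with oil. With the replicate number as a block they were 5 for malformed oil against water, 0 for dispersant against water, 1 for WAF Hi, 32 for CEWAF against WAF and 295 within WAF Hi. The numbers gave weak evidence of pairing, since deviations of arrays with the same number correlated at 0.04 on average.

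With the compared arrays alone, the counts were 159 for malformed against normal oil, 4 for malformed oil against water, 15 for dispersant against water (only 1 of them shared with the 9 reported), 0 for malformed oil against dispersant and 1 for WAF Lo. They were 2 for WAF Hi, 43 for CEWAF Hi, 158 for Hi against Lo, 12 for CEWAF against WAF, 21 for the interaction with preparation and 22 within WAF Hi. With a change of at least 2-fold they were 25 for malformed against normal oil, 9 for malformed oil against water, 5 for malformed oil against dispersant, 6 for WAF Hi, 36 for CEWAF Hi, 26 for Hi against Lo, 4 for CEWAF against WAF and 229 within WAF Hi.

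With scan day as a block, the counts were 8 for malformed oil against water, 0 for dispersant against water, 1 for WAF Hi, 36 for CEWAF against WAF and 1 for AWB against CLB. On scan day 1 alone they were 24 for malformed against normal oil, 8 for malformed oil against water, 156 for WAF Hi (6 of them shared with the 13 reported) and 18 for CEWAF Hi. They were 48 for Hi against Lo, 3 for CEWAF against WAF, 0 for the interaction with preparation and 1 for that with oil. On scan day 2 alone they were 0 for malformed against normal oil, 0 for malformed oil against dispersant, 2 for Hi against Lo, 0 for CEWAF against WAF, 1 for the interaction with preparation, 2 for that with oil and 0 within WAF Hi. Day 1 alone lost the list calls of the lens (adjusted p = 0.803), extracellular matrix (0.115) and mitochondrial (0.579) genes. Day 2 alone lost those of the sterol (0.0514) and ribosomal genes (0.159) with phenotype, the sterol genes with level (0.0849), the photoreceptor (0.219) and matrix genes (0.0583) with preparation and the neuron genes with oil (0.133). Among the arrays of day 2, 9 lists were called, and cyp1a within WAF Hi turned to -0.042. These zeros stood beside 790 to 2473 probes at an unadjusted p under 0.05 in limma. Comparisons whose groups were not on a scan day gave no value.

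Without the 2 least correlated arrays, the counts were 184 for malformed against normal oil, 15 for malformed oil against dispersant, 1 for WAF Hi, 148 for Hi against Lo, 25 for CEWAF against WAF, 15 for the interaction with preparation and 191 within WAF Hi. Without the 2 WAF Hi pools labelled normal they were 4 for malformed oil against dispersant, 1175 for WAF Hi, 1106 for Hi against Lo, 669 for CEWAF against WAF, 1439 for the interaction with preparation and 1 for that with oil. With hce as a covariate they were 48 for malformed against normal oil, 19 for malformed oil against dispersant, 1 for WAF Hi, 30 for Hi against Lo, 49 for CEWAF against WAF, 4 for the interaction with preparation and 44 within WAF Hi.

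Leaving out each array in turn gave 186 to 515 for malformed against normal oil, 5 to 28 for malformed oil against water, 0 to 12 for dispersant against water, 0 to 20 for malformed oil against dispersant, 1 to 572 for WAF Hi and 0 to 1 for CEWAF Lo. It gave 35 to 97 for CEWAF Hi, 143 to 969 for Hi against Lo, 14 to 320 for CEWAF against WAF, 25 to 804 for the interaction with preparation, 0 to 1 for that with oil, 3 to 593 within WAF Hi and 18 to 25 lists. The counts of WAF Lo, of normal oil against water and of AWB against CLB stayed at 0. The difference in cyp1a within WAF Hi turned to -0.054 without AWB_WAF_Hi 1 and reached 0.61 at the highest.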

Other observations

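Among the tests of this part, that of a shared effect of dispersant and CEWAF Hi was chosen only after its values were seen, and the test of scan day was then set before its own result was known.

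Between malformed and normal oil pools, single genes of further lists passed when adjusted over the list alone, although their lists did not pass or, for cyp3a40, cbr1, ppl and evpl, were too short to be tested. The fibrinogen chain gene fgg had a difference of -1.37 ± 0.41 and the angiopoietin gene angpt2 one of 0.55 ± 0.15 in the coagulation and vascular list. In bone and cartilage entpd5 was at -0.58 ± 0.16, in the retinoid and thyroid list the thyroid hormone receptor gene thra was at 0.38 ± 0.12 and the retinal reductase gene dhrs3 at 0.25 ± 0.09, and in the list of p53 and DNA damage the repair gene ogg1 (-0.31 ± 0.11) was lower. The muscle myosin gene mylpf was at -0.32 ± 0.11, the haem synthesis genes uros (-0.27 ± 0.09) and urod (-0.18 ± 0.07) were lower, and transferrin (LOC100144362) was at -0.50 ± 0.16. The gluconeogenic gene pck2 (0.31 ± 0.09), the chaperone gene dnajb9 (0.64 ± 0.17), the cytochrome gene cyp3a40 (0.68 ± 0.22), the carbonyl reductase gene cbr1 (0.19 ± 0.06) and the epidermal genes ppl (0.29 ± 0.10) and evpl (0.33 ± 0.14) were higher. None of these 16 genes passed over all genes in this comparison.

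The medians of the remaining lists in the same comparison lay between -0.21 and 0.12, and none passed by camera. They were -0.08 for fatty acid and lipid metabolism (adjusted p = 0.24), 0.10 for heat shock and protein folding (0.255), 0.12 for glycolysis, gluconeogenesis and hypoxia (0.256), -0.14 for lens crystallins (0.502), -0.09 for liver and plasma proteins (0.592), 0.05 for photoreceptor genes (0.692), -0.07 for neuron and glia (0.719), -0.04 for glutathione and antioxidant defence (0.746) and -0.02 for the mitochondrial respiratory chain (0.746). They were -0.01 for extracellular matrix (0.783), -0.11 for ion transport and osmoregulation (0.876), -0.21 for egg envelope and oestrogen response (0.909), 0.04 for haemoglobin and erythroid genes (0.919), 0.11 for p53 and DNA damage (0.949) and 0.01 for swim bladder and surfactant (0.987). For skeletal muscle the median was 0.07 and the mean -0.02 (0.746), and for immune genes the median was -0.02 and the mean 0.01 (0.919), so that median and mean differed in sign. Of the lists too short to test, dsp (0.13), aldh9a1 (0.03), the pancreas gene cpb1 (-0.36 ± 0.28, adjusted p = 0.628) and the intestine gene fabp2 (-0.20 ± 0.18, 0.684) did not pass.

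The hatching enzyme genes hce and hceb, both read through cross-hybridising probes, correlated at 0.9996 over the 31 arrays and are treated as 1 signal. Adjustment over their list alone therefore adjusts for little. Between WAF Hi and water hce differed by 4.27 ± 1.43 (adjusted p = 0.245, and 0.00771 over the list alone), and per array it ranged from -3.38 in CLB_CEWAF_Lo 2 to 5.50 in AWB_WAF_Hi 3. Within WAF Hi the ammonia transporter gene rh50 fell (-1.92 ± 0.41, adjusted p = 0.0181).

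One hypothesis was that dispersant alone shares an effect with CEWAF Hi. On the 200 probes with the smallest p for CEWAF Hi against CEWAF Lo, signed by that difference, the dispersant pools scored 0.425 ± 0.0403 (SD, n = 3), the water pools -0.0482 ± 0.128 (SD, n = 4) and the CEWAF Hi pools 0.776 ± 0.163 (SD, n = 6), and the lowest dispersant pool lay 0.281 above the highest water pool. The score of the CEWAF Hi pools was high by construction, because the probes were chosen and signed on those pools. Scan day, which parts the controls, is argued against as the cause, because the 12 WAF arrays of day 2 differed from those of day 1 by -0.0686 ± 0.0793 on this score, where at least 0.24 was needed. The slides of the controls differ too, and that was not tested. A shared effect of the dispersant may therefore account for part of the CEWAF Hi profile, such as cyp3a40 and dhrs13. Neither of these genes passed between dispersant and water. Other genes raised in CEWAF Hi did not share the shift. The level of c1qtnf7 was -2.2 to -1.8 in dispersant, -2.5 to -2.0 in water and -1.4 to -0.6 in CEWAF Hi pools. For cyp1a the difference of dispersant from water did not pass either. Malformation, which the dispersant and CEWAF Hi pools also share, stays open, although the malformed WAF Hi pools scored -0.107 ± 0.111 (SD, n = 4). The score is not specific to dispersant, because the normal pool CLB_WAF_Hi 3, which had none, scored 0.528, above all 3 dispersant pools.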
